A study of Homo sapiens with 2 samples.

How the data were processed

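Polyadenylated RNA of untreated HEK293 cells and of Synph-293 cells, which stably overexpress FLAG-tagged synphilin-1, was sequenced on an Illumina HiSeq instrument, per the labels' protocols. The protocols name both a stranded mRNA kit and a stranded total RNA kit, and describe purification of mRNA, in the series' design text with oligo(dT) beads. There were 2 libraries, 1 per line. The labels do not say whether Synph-293 is a single clone or a pool.

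The deposited table holds FPKM values, which the authors computed per gene with 2 decimals, under Ensembl gene IDs and symbols. Cufflinks 2.2.1 is listed in the submitters' processing notes, without its role. The aligner, the genome build, the annotation release, the filters and the number of reads are not given in the sources used here. FPKM divides by the mapped total and by an estimated transcript length, so a shift in a few abundant genes moves all others, and a gene's value depends on which transcript models share its reads. The column headings name each library by a single letter, H or S, and were matched to HEK293 and Synph-293 as the initial letters of the sample titles. IMMP1L had the highest value in both columns, with 4.08% of the FPKM sum in HEK293 and 6.76% in Synph-293. Low values did not fall on common steps. Over 842 genes at 0.3 to 1 FPKM in both libraries, at most 4.16% of the ratios shared a bin of 0.05 log2 units, against 5.67% for 2099 genes at 3 to 10 FPKM. Read numbers could therefore not be recovered, no count test was used, and no counting interval is given.

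The table has 21647 rows. In 28 of them the symbol had been turned into a date, and the symbol was restored from the Ensembl ID. Rows of one symbol were summed, which affected 129 symbols and left 21512. A symbol was tested when it reached 1 FPKM in at least one library, which held for 13290. The log2 ratio of a gene is log2 of (Synph-293 FPKM + 1) over (HEK293 FPKM + 1), so it understates the change of genes with low levels. A gene was called higher or lower by a fixed rule of size, a ratio of FPKM + 1 of at least 2-fold. With 1 library per line no test across replicates exists. Pearson and Spearman coefficients across genes describe the libraries.

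Genes named in the text follow a rule set before the data were examined. They are SNCAIP, the 12 highest and 12 lowest log2 ratios among genes at 5 FPKM or more in the higher library, leaving out unnamed loci and small RNA genes, and the members with the largest absolute log2 ratio of each gene list, up to 4 for a list outside the range of random lists and up to 2 for the others. A gene outside the rule is marked as such, and some genes within it are not reported here. In all 42 lists were fixed before the data were examined, covering protein quality control, stress, metabolism, signalling, cell cycle, neuronal function and markers of other cell types. The median log2 ratio of a list with at least 5 measured members was given its percentile among 10000 random lists of the same size, drawn from the same of 20 bins of mean expression. A list counts as outside the range when its median lies among the lowest or the highest 2.5% of the random medians. Some list members, among them all mitochondrially encoded genes and small structural RNAs of the lists, were not analysed here.

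Positions, gene types, transcript lengths and GC content come from GENCODE 29 on GRCh38, matched by Ensembl ID for 20500 rows, and may differ from the annotation behind the FPKM values. A transcript sequence was found for 97.9% of the tested symbols. Windows of 100 neighbouring genes, with the rest of a chromosome added to its last window and 94 genes in all on chromosome 21, were compared with 1000 random gene orders. The same steps were tested on simulated data for Synph-293 against HEK293 over 21512 genes. Of 200 changed genes, those changed by 1.5 log2 units were recovered in 91.0% of cases and those changed by 3 in 100.0%, and 0.25% of unchanged genes passed the 2-fold rule. All 10 lists of 25 genes shifted by 0.4 log2 units were found, and 2 of 40 lists without a shift lay outside the range. Simulated genes varied independently, with normally distributed noise. The simulation therefore does not measure how often co-regulated or neighbouring genes pass these rules by chance. The spread of the noise was set from the quartiles of the observed ratios within bins of mean expression. The 0.25% thus follows from this same comparison and is not an error rate between replicates. Changed genes and list members were drawn from levels above the 1 FPKM minimum, so recovery at the lowest levels was not measured.

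Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5 FPKM, no minimum level or one of 5 FPKM, ratios centred on their median, upper-quartile scaling, rescaling to TPM, a trimmed mean of log ratios, rows kept separate, protein-coding genes only, and 10 or 40 expression bins. Removing a smooth trend in GC content or transcript length (lowess, span 0.3) and subtracting the median of 100 neighbouring genes were added after the data were examined. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.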

Results

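RNA levels were compared between HEK293, an established line of human embryonic kidney cells, and Synph-293, a line made from HEK293 that stably overexpresses FLAG-tagged synphilin-1. Synphilin-1, encoded by SNCAIP, is found in the Lewy bodies of Parkinson disease. The comparison asks which transcripts differ when synphilin-1 is overexpressed. Each line was represented by 1 untreated library, so there are no replicates and no difference below has a replicate check or a p-value. Levels are FPKM, fragment counts scaled by transcript length and by the mapped total of the library, as the authors computed them. The FPKM of 21512 gene symbols summed to 582176 in HEK293 and 606363 in Synph-293, and 12667 and 13031 symbols reached 1 FPKM. The number of reads behind each library is unknown.

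SNCAIP was far higher in Synph-293, at 1431.69 FPKM against 1.5 FPKM in HEK293. This is a log2 ratio of 9.16 on the scale of FPKM + 1 and a 954-fold ratio of plain FPKM, in the direction given by the labels of both libraries. SNCAIP (ENSG00000064692) lies on the plus strand of chromosome 5 from 122311354 to 122464219 in GENCODE 29 on GRCh38. The values do not separate transcripts of the introduced copy from those of the cells' own gene. Over the 13290 symbols at 1 FPKM or more in at least one library, levels were otherwise close between the lines, with Pearson's r of 0.956 and Spearman's rho of 0.962 across genes, which are not independent replicates. Of these symbols, 491 were at least 2-fold higher in Synph-293 and 178 at least 2-fold lower, together 5.03%. At least 4-fold differences were seen for 80 and 25 symbols. Among genes whose higher level was 1 to 5 FPKM, 196 were higher and 48 lower, while at 100 FPKM or more the counts were 25 and 24. The count depends on the pseudocount, with 857 higher and 315 lower symbols at 0.1 FPKM and 129 and 63 at 5 FPKM. With a level of at least 5 FPKM required, 295 were higher and 130 lower.

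Among genes at 5 FPKM or more in the higher library, with unnamed loci and small RNA genes left out, the largest ratios in favour of Synph-293 after SNCAIP were those of ADAMTS16, a secreted metalloprotease, at 0.6 FPKM in HEK293 and 236.42 FPKM in Synph-293, and CLHC1, at 18.05 and 2708.78 FPKM. PPP1R37, EFTUD1, PIGQ and CASKIN1 followed with log2 ratios of 6.30, 5.79, 5.49 and 5.17. RBFOX3, a splicing factor of mature neurons also known as NeuN, was at 0.15 and 35.81 FPKM, and LGR5, a receptor for R-spondins that marks several kinds of stem cell, was at 2.33 and 79.93 FPKM. FAM111B, ZNF711 and KRBOX1 completed the 12 highest, with log2 ratios of 4.64, 4.11 and 4.10. In the other direction and under the same limits UNC13D, which primes secretory granules for release, was at 105.41 FPKM in HEK293 and 0.75 FPKM in Synph-293. MLLT10, a chromatin cofactor, was at 406.76 and 15.59 FPKM, C11orf95 at 370.46 and 14.41 FPKM, and BAALC at 26.16 and 0.5 FPKM. C10orf10, POU6F1 and PARP14 had log2 ratios of -3.81, -2.81 and -2.69, and ZBTB20, a transcriptional repressor, was at 11.34 and 0.54 FPKM. DYRK1A, a protein kinase encoded on chromosome 21, was at 164.31 and 24.7 FPKM. FAM71F2 and RDH10, a retinol dehydrogenase, were also among the 12 lowest, with log2 ratios of -2.57 and -2.51. An annotated transcript shorter than 300 nt was present for 8 of the 11 highest genes after SNCAIP and for 5 of the 12 lowest. Some of the unnamed loci had larger ratios, and are given here after their values were seen. CTD-2313N18.2 was at 0.72 and 5832.01 FPKM, a log2 ratio of 11.73. LINC00674 was at 1083.69 and 1.36 FPKM, AC018865.8 at 353.05 and 0.1 FPKM and RP11-807H7.1 at 1948.89 and 5.53 FPKM, with log2 ratios of -8.84, -8.33 and -8.22. Each of these loci has an annotated transcript shorter than 300 nt.

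**Figure D1:**
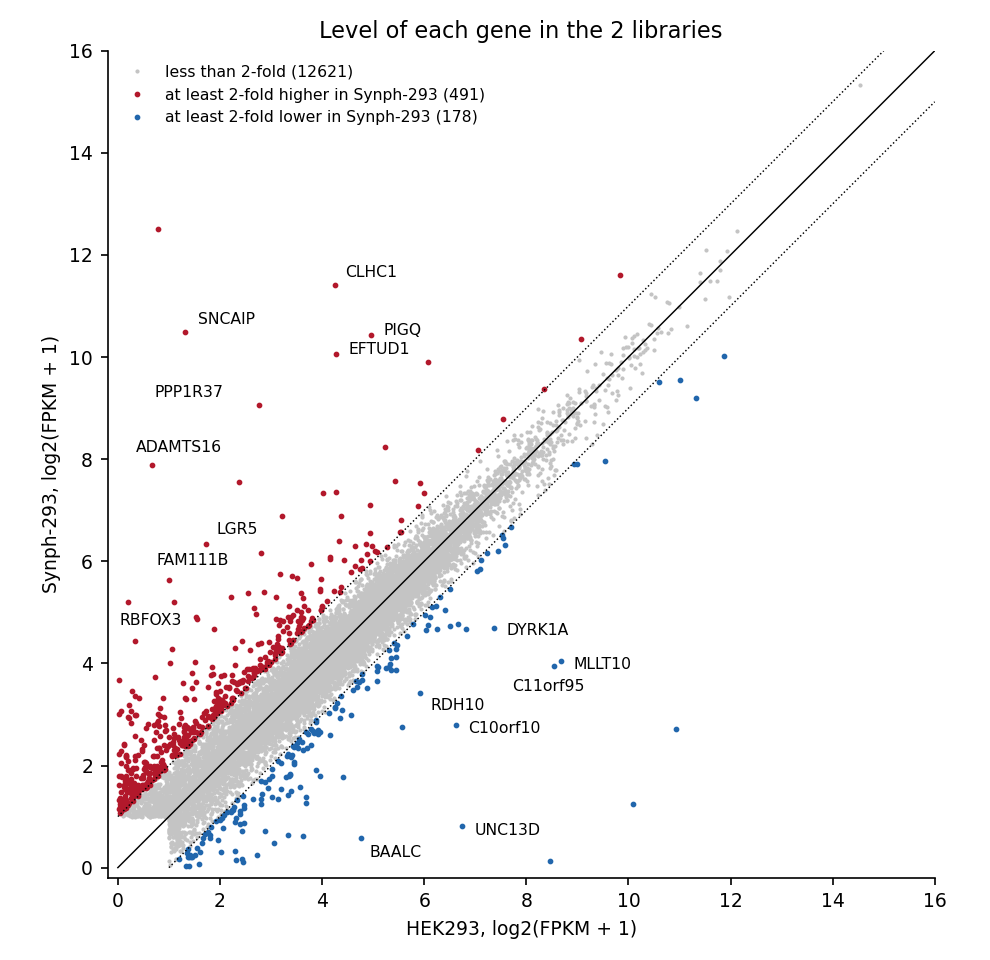
Level of each of the 13290 gene symbols at 1 FPKM or more in at least one library, as log2(FPKM + 1) in HEK293 (x axis) and in Synph-293 (y axis), 1 library each. The solid line marks equal levels and the dotted lines a 2-fold ratio of FPKM + 1, with 491 symbols above (red) and 178 below (blue), and SNCAIP lies at 1.5 FPKM in HEK293 and 1431.69 FPKM in Synph-293.

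Gene lists fixed before the data were examined gave 37 sets with at least 5 measured members. The median log2 ratio of a list was placed among 10000 random lists of the same size and mean expression, as a description of these libraries. In 5 lists the median lay among the highest 2.5% of the random medians and in 7 among the lowest 2.5%, and 25 lists lay inside that range. If genes varied independently, 1.9 lists in all would lie outside it. Random lists were drawn gene by gene, while neighbouring genes shared their ratios here and members of a pathway may do so too. An excess over 1.9 is therefore not evidence against chance.

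Neuronal genes were higher in Synph-293 as a group. Of 30 measured members, 22 had a log2 ratio above 0, 8 were at least 2-fold higher, and the median log2 ratio was 0.66, at percentile 100.0 of random lists. The median was 0.34 with a pseudocount of 5 FPKM and 0.40 with no minimum level, at percentile 100.0 in both cases. Besides RBFOX3, the largest ratios belonged to KIF1A, a motor of synaptic vesicle precursors, at 3.88 FPKM in HEK293 and 18.82 FPKM in Synph-293, and ENO2, the neuronal enolase, at 20.49 and 64.22 FPKM. ELAVL2, a neuronal RNA-binding protein, was at 0.02 and 1.49 FPKM. MAP2, the dendritic microtubule protein, was the 1 member at least 2-fold lower, at 9.12 and 3.67 FPKM, and is named here after its value was seen. Too few intermediate filament genes of neurons were measured to place that list, but NEFL, the light neurofilament subunit, was at 12.78 and 60.85 FPKM, and VIM at 63.32 and 80.49 FPKM. Not every list with a link to neurons differed. The medians of the SNARE and synaptic vesicle trafficking list (-0.04, percentile 25.4), the dopamine synthesis, transport and receptor list (percentile 27.0) and the astrocyte and glial list (-0.09, percentile 17.8) lay inside the range of random lists. Of their members 37 of 39, 12 of 26 and 7 of 17 were measured, so the dopamine and glial lists were assessed only in part. TH, DDC and SLC6A3, outside the naming rule, were among the dopamine genes not measured. Within these lists STXBP2 was lower, at 6.07 and 1.73 FPKM, and DNM1 was at 5.25 and 10.83 FPKM. With a pseudocount of 5 FPKM the log2 ratios of ELAVL2 (0.37), MAP2 (-0.70) and STXBP2 (-0.72) fell short of 2-fold, and with 0.1 FPKM that of DNM1, 0.92, came to 1.03.

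The list of cadherins, protocadherins and ephrins, which also holds Eph receptors (EPHA and EPHB genes), was higher as a group too. Its members hold cells together and guide their contacts. Of 27 measured members, 7 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 ratio of 0.37 at percentile 99.7. EPHA7 was at 0.01 FPKM in HEK293 and 11.71 FPKM in Synph-293, CDH13 at 0.21 and 9.93 FPKM, CDH4 at 0.22 and 2.88 FPKM and EPHB1 at 2.33 and 7.43 FPKM. EPHA3, the member that was lower and was not picked by the naming rule, was at 10.67 and 4.75 FPKM. CDH4 (0.59), EPHB1 (0.76) and EPHA3 (-0.68) had log2 ratios short of 2-fold with a pseudocount of 5 FPKM, and that of EPHA3 was -0.96 once a trend in GC content was removed.

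WNT pathway targets and regulators were higher in Synph-293, with 21 of 25 measured members above 0 and a median log2 ratio of 0.37 at percentile 99.8. The at least 2-fold higher members were LGR5, SFRP1, a secreted WNT antagonist, at 4.98 and 18.21 FPKM, and WNT5A, a ligand, at 3.06 and 7.58 FPKM. TCF7, a transcription factor of the pathway, was at 4.77 and 10.03 FPKM. Immediate early and MAP kinase feedback genes had a median log2 ratio of 0.45 at percentile 99.98, with 24 of 30 members above 0. Only ETV4 (0.63 and 2.95 FPKM) and ETV1 (0.31 and 2.06 FPKM), transcription factors induced by ERK signalling, passed the 2-fold rule upward, and DUSP2, a phosphatase of MAP kinases, passed it downward at 1.62 and 0.15 FPKM. IER3 was at 11.57 and 22.82 FPKM. The median of the immediate early list was 0.28 with a pseudocount of 5 FPKM, where the log2 ratios of WNT5A (0.64), ETV4 (0.50), ETV1 (0.41) and DUSP2 (-0.36) fell short of 2-fold. With 0.1 FPKM the log2 ratio of TCF7, 0.93, came to 1.06.

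Chaperones of the endoplasmic reticulum and factors of ER-associated degradation were lower in Synph-293. Of 26 measured members, 21 had a log2 ratio below 0, and the median of -0.23 lay at percentile 0.12. The protein disulfide isomerases PDIA4 and PDIA3 were at least 2-fold lower, at 172.88 and 72.17 FPKM and at 207.96 and 100.5 FPKM in HEK293 and Synph-293. The log2 ratio of PDIA3, -1.04, came to -0.98 once a trend in GC content was removed. PDIA3 lies in a window of neighbouring genes on chromosome 15 whose median was -0.29. HYOU1, a large ER chaperone, was at 132.07 and 67.73 FPKM. Its log2 ratio of -0.95 came to -1.02 under TPM scaling and -1.03 under scaling by a trimmed mean of log ratios, and passed 2-fold with the GC trend removed as well. DERL3, a component of the degradation machinery, went the other way, at 6.32 and 41.2 FPKM. Targets of ATF4, the transcription factor of the integrated stress response, were lower too, with 20 of 25 members below 0, 4 at least 2-fold lower and a median of -0.26 at percentile 0.06. Among them ALDH1L2, a mitochondrial folate enzyme, was at 11.91 and 1.39 FPKM, NUPR1 at 10.59 and 4.05 FPKM and the cystine transporter SLC7A11 at 3.84 and 1.27 FPKM. The other member at least 2-fold lower, named after its value was seen, was SLC7A5 at 89.74 and 43.03 FPKM. GDF15, a secreted stress cytokine, was higher, at 1.16 and 4.08 FPKM. NUPR1 (-0.78), SLC7A11 (-0.50), SLC7A5 (-0.98) and GDF15 (0.56) had log2 ratios short of 2-fold with a pseudocount of 5 FPKM.

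NRF2 antioxidant genes had a median log2 ratio of -0.21 at percentile 0.46, with 15 of 23 members below 0 and 8 above 0, 4 at least 2-fold lower and 1 at least 2-fold higher. The median was -0.43 once the median of neighbouring genes was subtracted. The lower members were HMOX1, which degrades haem, at 19.87 and 7.53 FPKM, GCLM, a subunit of the first enzyme of glutathione synthesis, at 32.97 and 14.27 FPKM, the quinone reductase NQO1 at 18.02 and 7.83 FPKM, and SLC7A11, which the ATF4 list also holds. None of these calls held with a pseudocount of 5 FPKM, where the log2 ratios were -0.99, -0.98, -0.84 and -0.50. The higher member, named after its value was seen, was AKR1C2 at 0.32 and 1.7 FPKM, a log2 ratio of 1.03 that came to 0.33 with a pseudocount of 5 FPKM and 0.99 under scaling by a trimmed mean. In the list of cytosolic heat shock chaperones no member passed the 2-fold rule, and the median of -0.19 lay at percentile 0.655. Under scaling by a trimmed mean it was -0.31. Its largest ratios were those of the small heat shock proteins HSPB8 (30.32 and 17.84 FPKM), HSPB1 (110.01 and 66.29 FPKM) and CRYAB (1.16 and 0.37 FPKM) and of BAG1 (17.6 and 10.44 FPKM). The log2 ratio of CRYAB, -0.66, came to -1.42 with a pseudocount of 0.1 FPKM and to -0.20 with 5 FPKM. Autophagy and lysosome genes had a median of -0.13 at percentile 1.76, again with no member past 2-fold, and one of -0.21 under scaling by a trimmed mean. SQSTM1, the autophagy receptor p62, was at 112.24 and 58.16 FPKM, the lysosomal membrane protein LAMP1 at 91.45 and 49.53 FPKM, the cathepsin gene CTSL1 at 60.57 and 34.99 FPKM and ATP6V1H, a proton pump subunit, at 36.54 and 21.36 FPKM. Under scaling by a trimmed mean the log2 ratio of SQSTM1, -0.94, came to -1.01, and to -1.02 once a trend in GC content was removed.

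**Figure D2:**
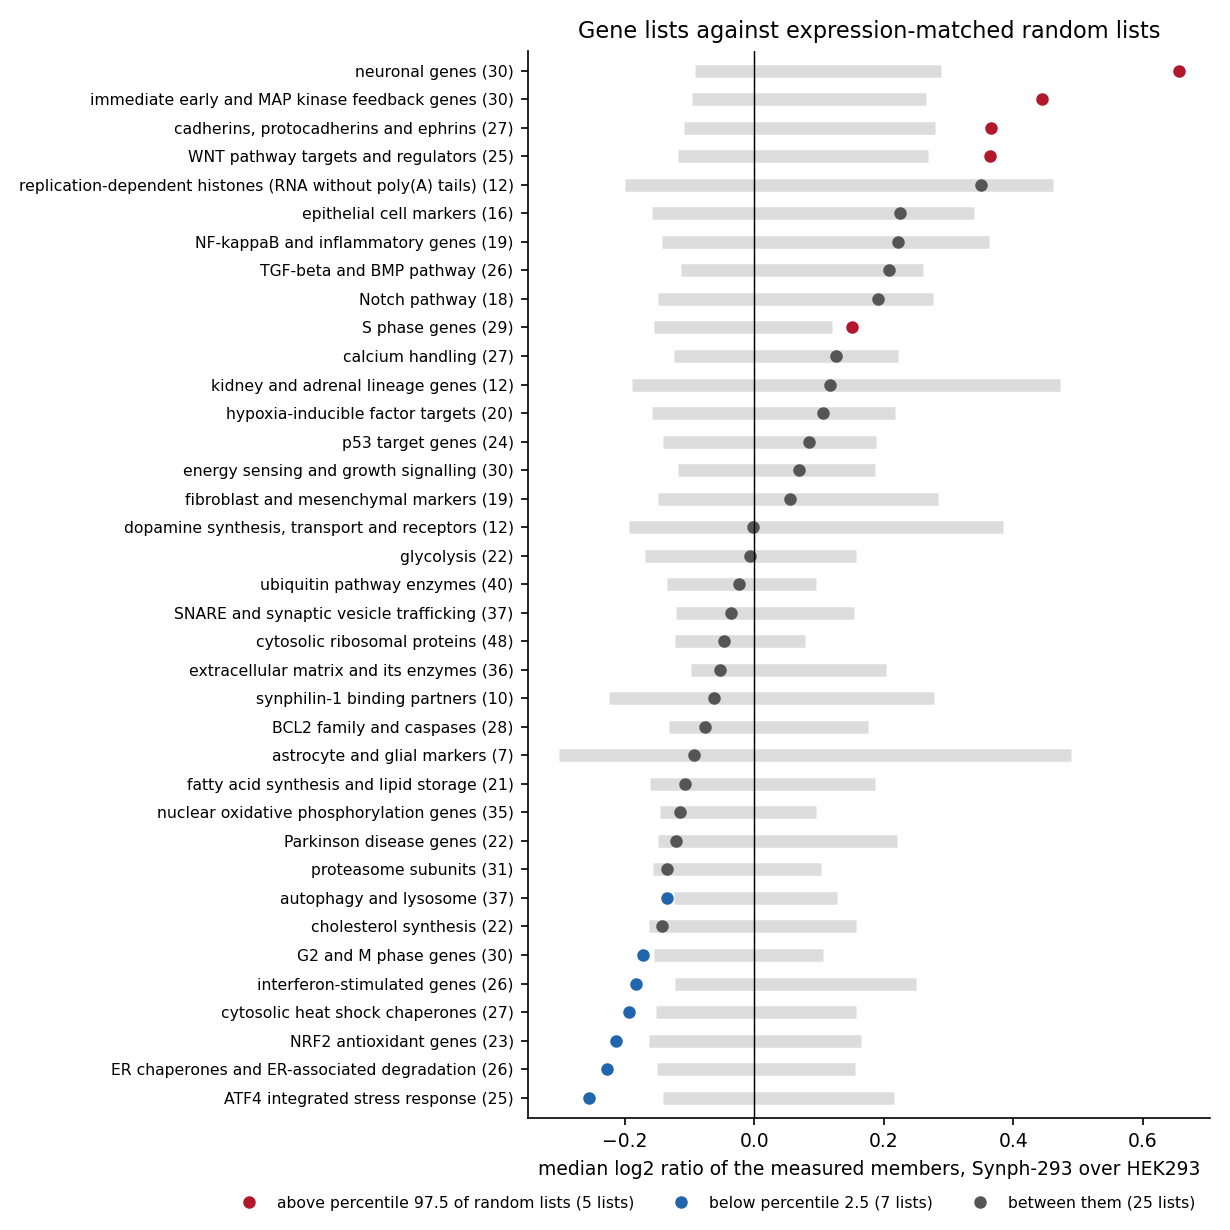
Median log2 ratio of Synph-293 over HEK293 for the 37 gene lists with at least 5 measured members (points, number of measured members in brackets), with grey bars over the medians of 10000 expression-matched random lists without the lowest and highest 2.5%. Red points lie above the bar (5 lists, neuronal genes highest at 0.66), blue points below it (7 lists, ATF4 integrated stress response lowest at -0.26) and dark grey points inside it (25 lists).

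Cell cycle lists lay on opposite sides, with small shifts. S phase genes had a median log2 ratio of 0.15 at percentile 99.1 and G2 and M phase genes one of -0.17 at percentile 1.4, and no member of either list passed the 2-fold rule. The S phase median was 0.09 under TPM scaling and 0.08 under scaling by a trimmed mean, still above the range of random lists. UHRF1, RRM1, CCNE1 and CHAF1A had the largest ratios in the first, from 0.59 to 0.64. Those in the second were UBE2C, CKS2, DLGAP5 and NUSAP1, from -0.53 to -0.44. RRM1, CCNE1 and CHAF1A lie in windows of neighbouring genes, described below, whose medians were 0.49, 0.40 and 0.30. The S phase list stayed at percentile 99.64 once the median of neighbouring genes was subtracted. The G2 and M phase list came to percentile 3.44 once a trend in GC content was removed and to 8.96 once the median of neighbouring genes was subtracted.

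Interferon-stimulated genes were split. The median log2 ratio of 26 members was -0.18, at percentile 0.58, whereas their mean was 0.25. The members with the largest ratios were higher. The antigen-presenting gene HLA-B was at 1.91 FPKM in HEK293 and 28.36 FPKM in Synph-293, and the membrane antiviral factors IFITM1 and BST2 at 4.4 and 20.61 FPKM and at 29.47 and 93.22 FPKM. IFITM2, at 7.48 and 16.87 FPKM, and IFIT1, at 4.45 and 1.66 FPKM and the 1 member at least 2-fold lower, were named after their values were seen. Their log2 ratios, 0.81 and -0.50 with a pseudocount of 5 FPKM, then fell short of 2-fold, and that of IFIT1 was -0.97 once a trend in GC content was removed. IFITM1 and BST2 lie in windows of neighbouring genes, described below, whose medians were 0.49 and 0.40. With genes of at least 5 FPKM alone the median of the list was 0.12, at percentile 78.2. The median was -0.10, at percentile 4.55, once a trend in transcript length was removed and -0.08, at percentile 4.25, once the median of neighbouring genes was subtracted. It was -0.06 with no minimum level and -0.11 with a pseudocount of 5 FPKM, below the range of random lists in both cases.

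**Figure D3:**
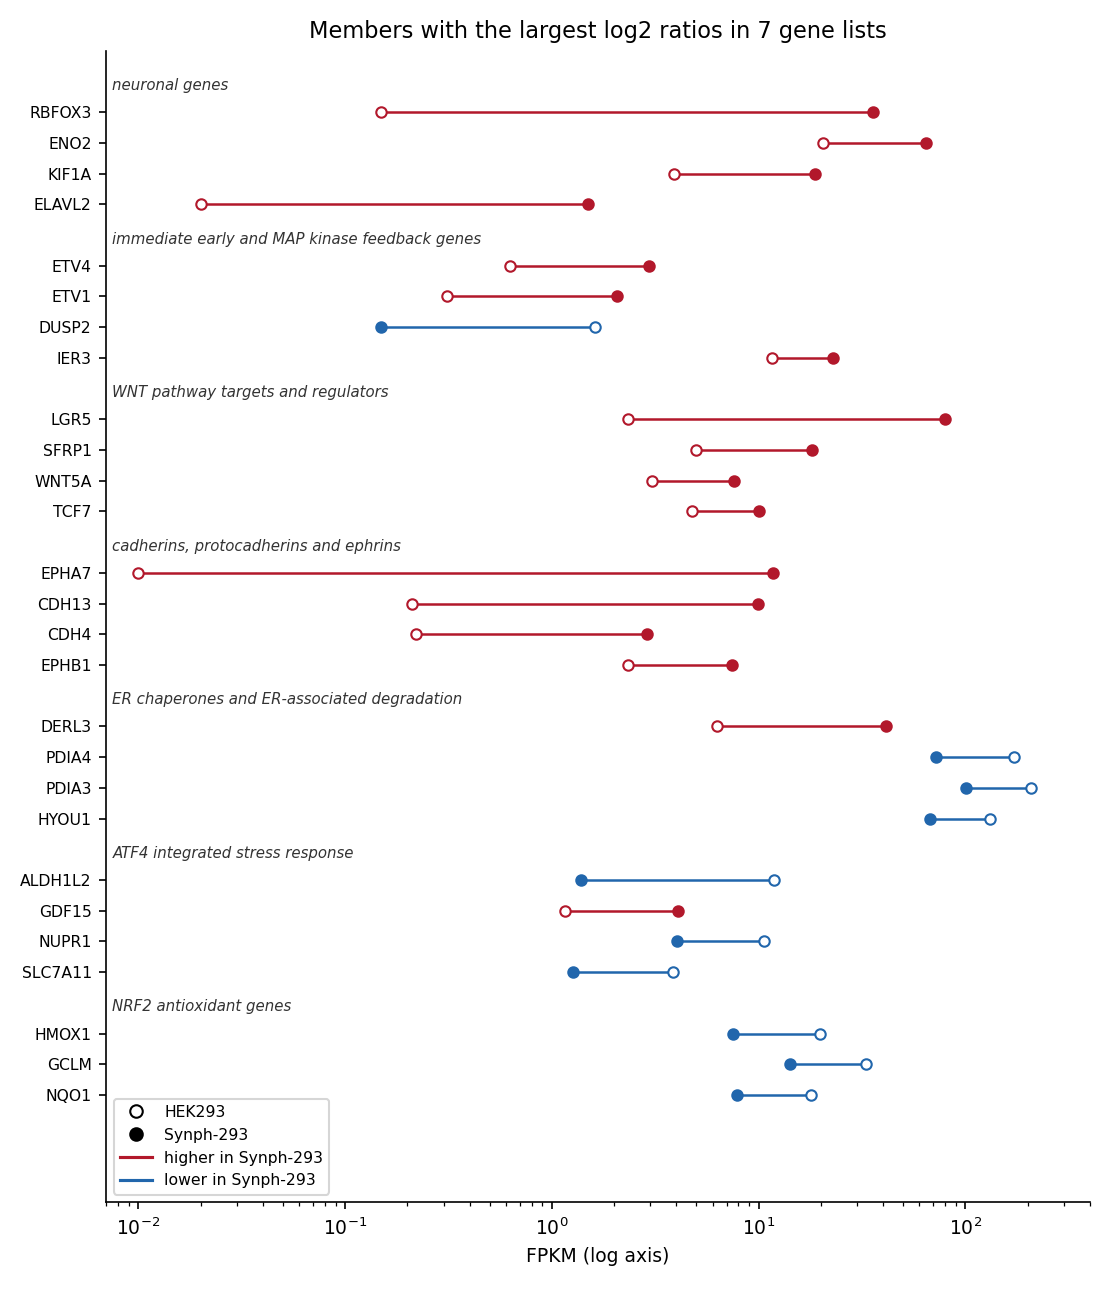
FPKM in HEK293 (open circles) and Synph-293 (filled circles) on a log axis, 1 library each, for the members with the largest log2 ratios in 7 of the 12 lists that lay outside the range of random lists, each gene drawn once. Red lines join genes higher in Synph-293, such as RBFOX3 at 0.15 and 35.81 FPKM, and blue lines genes lower there, such as ALDH1L2 at 11.91 and 1.39 FPKM.

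Binding partners of synphilin-1 and Parkinson disease genes lay inside the range of random lists. The partners had a median log2 ratio of -0.06 at percentile 26.2, with no member past 2-fold. The ubiquitin ligase RNF19A was at 18.05 FPKM in HEK293 and 10.26 FPKM in Synph-293, and the kinase LRRK2 at 2.62 and 1.51 FPKM. Parkinson disease genes lay at percentile 4.62 with a median of -0.12. MAPT, which encodes tau, was the 1 member at least 2-fold higher, at 3.03 and 8.03 FPKM, and SNCB was at 0.23 and 1.22 FPKM. With a pseudocount of 5 FPKM the log2 ratio of MAPT, 1.16, came to 0.70, short of 2-fold, while that of SNCB, 0.85, came to 1.11 under TPM scaling and passed 2-fold with a pseudocount of 0.1 FPKM as well. Proteasome subunits lay at percentile 6.34 and ubiquitin pathway enzymes at percentile 45.4. PSMA2 and PSMD13 differed most among the former, with log2 ratios of -0.68 and 0.62, and CUL1 and UBE2S among the latter, with -0.90 and 0.56. Nuclear oxidative phosphorylation genes lay at percentile 7.56, where UQCRB, a subunit of complex III, was at 186.33 and 87.37 FPKM and NDUFA4 at 91.19 and 47.7 FPKM. Genes of the BCL2 family and caspases lay at percentile 10.8, with BIRC3 at 2.75 and 0.89 FPKM and CASP6 at 23.33 and 11.68 FPKM. Their log2 ratios of -0.99 and -0.94 came to -1.21 and -1.02 under TPM scaling and to -1.02 and -1.01 under scaling by a trimmed mean, and that of BIRC3 to -1.53 with a pseudocount of 0.1 FPKM.

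Other signalling lists also lay inside that range, though some members differed widely. HEY1, a target of Notch, was at 99.74 and 26.32 FPKM while the ligand DLL1 was at 2.43 and 6.72 FPKM, and the Notch list lay at percentile 89.1. BMP2 was at 0.76 and 6.79 FPKM and INHBB at 3.55 and 10.67 FPKM in the TGF-beta and BMP list, at percentile 92.0. IGF2, a growth factor, was at 0.65 and 12.37 FPKM and its binding protein IGFBP5 at 1.53 and 8.92 FPKM in the energy sensing and growth signalling list, at percentile 72.6. In the NF-kappaB and inflammatory list, at percentile 80.4, the chemokines CCL20 and CXCL1 were at 0.16 and 2.16 FPKM and at 0.13 and 1.38 FPKM. TNFRSF10B, a death receptor, was at 29.56 and 63.49 FPKM and CDKN1A at 58.2 and 94.49 FPKM among p53 targets, at percentile 78.8. Calcium handling genes lay at percentile 83.9, with RYR2 and CACNA1C at log2 ratios of 1.48 and 1.08. With a pseudocount of 5 FPKM the log2 ratios of DLL1 (0.66), INHBB (0.87), CCL20 (0.47), CXCL1 (0.31), TNFRSF10B (0.99), RYR2 (0.90) and CACNA1C (0.44) fell short of 2-fold.

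Metabolic lists gave percentiles of 50.8 for glycolysis, 81.3 for hypoxia-inducible factor targets, 4.33 for cholesterol synthesis and 9.48 for fatty acid synthesis and lipid storage. SLC2A3, a glucose transporter, was at 80.15 and 45.67 FPKM, SQLE at 95.88 and 60.2 FPKM and PFKFB4 at 1.73 and 3.39 FPKM. DGAT1, which makes triglycerides, was at 12.72 and 27.37 FPKM. Its log2 ratio of 1.05 came to 0.87 with a pseudocount of 5 FPKM, 0.98 under scaling by a trimmed mean of log ratios and 0.93 once a trend in GC content was removed. Cytosolic ribosomal proteins lay at percentile 25.3. RPS19 was at 322.34 and 663.66 FPKM and RPS25 at 619.48 and 315.43 FPKM. The log2 ratio of RPS19, 1.04, came to 0.98 under TPM scaling, 0.97 under scaling by a trimmed mean and 0.97 with the GC trend removed, and that of RPS25, -0.97, to -1.03 under TPM scaling and -1.05 under scaling by a trimmed mean.

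Markers of other cell types lay inside the range in the main setting, where they could be placed. Epithelial markers lay above it with a pseudocount of 5 FPKM (98.2) or a minimum of 5 FPKM (99.0), and replication-dependent histones with that minimum (99.98). Extracellular matrix genes lay below it with the GC trend removed (0.89). Epithelial markers were at percentile 87.0, with KRT17, a keratin, at 10.34 and 50.2 FPKM and ESRP1, an epithelial splicing factor, at 3.94 and 0.11 FPKM. Fibroblast and mesenchymal markers were at percentile 50.1, with ACTA2 at 9.95 and 3.18 FPKM and COL3A1 at 1.43 and 4.4 FPKM. Extracellular matrix genes were at percentile 8.81, with TIMP3 and VCAN at log2 ratios of 1.41 and 1.40. Kidney and adrenal lineage genes were at percentile 46.2, with PAX2, a kidney transcription factor, at 0.18 and 2.12 FPKM and SALL1 at 1.3 and 4.67 FPKM. Of immune and endothelial markers only 4 and 2 reached 1 FPKM, EGFL7 being the highest at 23.57 and 13.79 FPKM, with CD8A at 1.01 and 0.52 FPKM. Replication-dependent histones, whose transcripts mostly lack poly(A) tails, were at percentile 91.9. HIST1H2BK was at 5.96 and 70.82 FPKM and HIST1H1C at 12.26 and 32.2 FPKM. The log2 ratios of ESRP1 (-0.81), ACTA2 (-0.87), COL3A1 (0.55), PAX2 (0.46) and SALL1 (0.62) fell short of 2-fold with a pseudocount of 5 FPKM.

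Along the chromosomes, neighbouring genes shared their ratios over long stretches. The 9664 genes at 5 FPKM or more in both libraries were cut into 86 windows of 94 to 189 neighbours by their GENCODE 29 positions on GRCh38. On chromosome 7, all 100 genes from 0.5 to 33.1 Mb, from PDGFA to NT5C3A, had a log2 ratio below 0, 8 of them being at least 2-fold lower in Synph-293, with a median log2 ratio of -0.65 and quartiles of -0.77 and -0.48, while the next window, from 33.1 to 76.4 Mb, had a median of -0.14. On chromosome 11, the window from 0.1 to 18.4 Mb had a median of 0.49 with 87 of 100 genes above 0, and the window from 76.4 to 134.4 Mb a median of -0.31 with 139 of 164 below 0. Chromosome 19 had a median of 0.33 over 606 genes, 494 of them above 0, and chromosome 15 one of -0.26 over 321 genes, 50 of them above 0. Several genes named above lie in these stretches and were shifted the same way, so their ratios cannot be credited to their lists alone. NDUFA4 lies in that of chromosome 7. PSMD13, RRM1, IFITM1 and IGF2 lie in the higher one of chromosome 11, and HYOU1, RPS25, BIRC3 and CRYAB in its lower one. RPS19, CCNE1, CHAF1A, BST2 and GDF15 lie on chromosome 19, and PDIA3 and NUSAP1 on chromosome 15. Others went the other way, such as ETV1 in the chromosome 7 stretch, STXBP2 on chromosome 19 and EFTUD1 on chromosome 15. The SD of the window medians was 0.183, against at most 0.0454 in 1000 random gene orders.

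**Figure D4:**
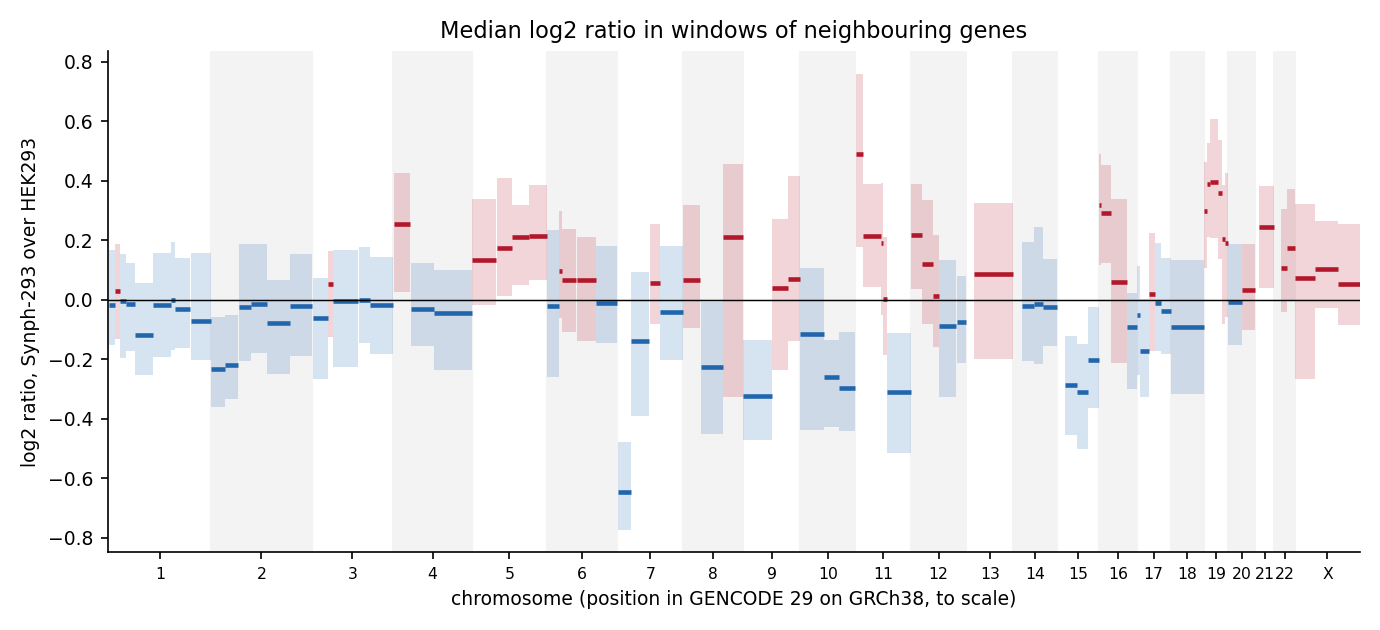
Median log2 ratio of Synph-293 over HEK293 (thick lines) and its quartiles (shaded) in 86 windows of 94 to 189 neighbouring genes at 5 FPKM or more in both libraries, along chromosomes 1 to 22 and X drawn to scale. The lowest window is chromosome 7 from 0.5 to 33.1 Mb, with a median of -0.65, and the highest is chromosome 11 from 0.1 to 18.4 Mb, with a median of 0.49.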

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

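The corrections for GC content, transcript length and neighbouring genes were chosen after the data were examined. No paired analysis was possible because each line has 1 library. The pseudocount moved the number of called genes most. With 0.1 FPKM in place of 1 FPKM, 857 symbols were at least 2-fold higher in Synph-293 and 315 at least 2-fold lower, and with 5 FPKM 129 and 63, since a pseudocount weighs most on low levels. A minimum of 5 FPKM left 295 higher and 130 lower symbols among the 10548 tested, fewer because fewer genes entered. The other settings gave 433 to 598 higher and 154 to 267 lower symbols, and 67.2% to 74.5% of the called symbols were higher in Synph-293 under all settings. The scale factors of Synph-293 relative to HEK293 were -0.07 to 0.0046 in log2 units. TPM scaling also changes both levels against the fixed pseudocount, so it moved genes with low levels by more. The log2 ratio of EPHA7 came from 3.65 to 4.32 and that of ESRP1 from -2.15 to -2.72. The log2 ratio of SNCAIP level stayed between 7.79 and 9.81. Of 123 other genes picked by the naming rule, 77 passed the 2-fold rule, and 29 of them no longer did with a pseudocount of 5 FPKM, 4 with the GC trend removed, 2 under the trimmed mean and 1 under TPM scaling. Of the others, 7 passed it with a pseudocount of 0.1 FPKM, 7 under TPM scaling, 5 under the trimmed mean and 2 with the GC trend removed. Between 11 and 15 gene lists lay outside the range of random lists. All 12 of the original lists stayed on their side under both pseudocounts, the scalings, both bin numbers and with no minimum level. The interferon-stimulated list moved inside the range with a minimum of 5 FPKM, with the length trend removed and with the median of neighbours subtracted, and the G2 and M phase list with the GC trend removed and with the median of neighbours subtracted. The cause was not tested. Some medians moved by more than 1.5 times while the list stayed outside the range. With a pseudocount of 5 FPKM neuronal genes came from 0.66 to 0.34, immediate early genes from 0.45 to 0.28 and interferon-stimulated genes from -0.18 to -0.11. With no minimum level neuronal genes came to 0.40 and interferon-stimulated genes to -0.06. Under the trimmed mean S phase genes came from 0.15 to 0.08, heat shock chaperones from -0.19 to -0.31 and autophagy and lysosome genes from -0.13 to -0.21, and under TPM scaling S phase genes to 0.09. With the median of neighbours subtracted NRF2 genes came from -0.21 to -0.43. The median of neighbours also brought proteasome subunits to percentile 1.64, cholesterol synthesis to 0.63 and p53 targets to 98.5, and the Notch list to 98.2 and the TGF-beta and BMP list to 98.5. Other lists left the range too. With the GC trend removed these were cholesterol synthesis at 0.91 and extracellular matrix genes at 0.89. With a pseudocount of 5 FPKM epithelial markers came to 98.2, and with no minimum level the TGF-beta and BMP list to 97.86. With a minimum of 5 FPKM epithelial markers came to 99.0, the Notch list to 98.75, the TGF-beta and BMP list to 97.85 and replication-dependent histones to 99.98. Because reads per library are unknown, no limit from depth can be set on genes with low levels.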

Other observations

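Of the tests in this part, the count of adjacent gene pairs was chosen after its result was seen, and the corrections for GC content, transcript length and neighbouring genes were added after the data were first examined. Some of the genes past the 2-fold rule sit side by side. Here and below only tested symbols count as neighbours, so genes under 1 FPKM in both libraries may lie between them. On chromosome 11, 7 adjacent genes between 369796 and 564021 (GENCODE 29 on GRCh38) were each at least 2-fold higher in Synph-293, namely B4GALNT4, PKP3, SIGIRR, PTDSS2, RNH1, HRAS and RASSF7, with HRAS at 17.75 and 41.69 FPKM. Farther along, between 58878302 and 59208587, GLYATL1P2, GLYATL1, FAM111B, FAM111A and DTX4 were all at least 2-fold higher. On chromosome 12 the keratin genes KRT75, KRT6A and KRT5 were higher together, and on chromosome 8 TMEM67, PDP1 and GEM lower together. Except for FAM111B, which the naming rule picked, these genes were named after their values were seen. With a pseudocount of 5 FPKM the log2 ratios of PKP3, SIGIRR, RNH1, RASSF7, GLYATL1P2, GLYATL1, KRT75, KRT6A and KRT5 fell short of 2-fold, as did those of TMEM67 (-0.97) and GEM (-0.93), and that of SIGIRR was 0.94 with the GC trend removed.

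Long stretches of neighbouring genes moved together. Chance order of the genes past the 2-fold rule is argued against. Of adjacent pairs that do not overlap, 54 were both at least 2-fold higher (51 pairs) or both at least 2-fold lower (3 pairs). The highest count in 1000 random orders was 31. This count covers adjacent pairs, not long stretches, and includes related genes side by side, such as the keratins above. A trend in GC content is argued against as well, because the SD of the window medians was 0.1697 after its removal, above the 0.0451 that random orders reached at most. The spread before that removal, 0.183 against a median of 0.037 for random orders, is the pattern itself. A change of gene dosage over long segments in one of the lines and regulation shared by neighbours would both widen it, so they cannot be told apart by it and both stay open. Genomic DNA was not analysed here. Also open is which line carries a change and whether it came with synphilin-1 or with the isolation of the line.

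The lower medians of the ER chaperone, ATF4 and NRF2 lists were weighed together, as 73 genes with a pooled median log2 ratio of -0.24, of which 55 lay below 0. The pooled median was -0.24 with the GC trend removed, -0.23 with the length trend removed and -0.28 with the median of neighbouring genes subtracted, each below -0.08, the bound of the lowest 2.5% of matched random lists in each case. These values argue against GC content, transcript length and gene dosage over long segments as the whole cause. Whether the lower medians came with synphilin-1, the culture or the clone was not tested, as each line has 1 library.

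Log2 ratios of at least 3 in size, SNCAIP aside, were found for 35 genes. Of these, 60.0% have an annotated transcript shorter than 300 nt, against a median of 11.4% in expression-matched random sets, of which the highest 2.5% began at 25.7%. FPKM estimates of very short transcript models can be unstable, so part of these ratios may come from the assignment of reads to such models and not from the level of the gene. Another gene on the same strand overlapped 45.7% of them, against a median of 34.3% in random sets, of which the highest 2.5% began at 51.4%, so with 35 genes this cannot be told apart from chance. The unnamed loci CTD-2313N18.2, LINC00674, AC018865.8 and RP11-807H7.1 are among the 35 and have such a short transcript. RBFOX3, LGR5 and HLA-B, named above with the neuronal, WNT and interferon-stimulated lists, are among the 35 and have one too. HLA-B also overlaps 5 genes on its strand, HLA-C among them. EPHA7 (0.01 and 11.71 FPKM), FAM111B and ZNF711 are among those of the 35 with no transcript that short. No biological explanation was tested.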
